A study of Rattus norvegicus with 47 samples.

How the data were processed

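Gene expression was measured in whole blood of adult Sprague Dawley rats with an Illumina rat bead array, 1 array per rat and 1 colour. Per the labels' protocols, blood was taken into PAXgene tubes, which lyse the cells and fix their RNA, globin messenger RNA was depleted, and biotinylated cRNA was hybridised. The labels gave each sample its own rat, so the p-values measure the spread between animals. The series held 47 arrays in 6 groups, which were the control, minimal response and extreme response animals of each sex. The response classes were the submitters' own grouping of exposed rats by behaviour.

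The authors deposited 1 non-normalized intensity per probe and array, together with a detection p-value, per the file headers. The authors also deposited a table of log2 values, of unstated origin, for 46 samples. Its largest difference from quantile-normalized log2 intensities without background correction was 5e-09, and each column had a median of 6.59, so its scale and normalization were settled by recomputation and no direction or centring stayed open. The scanner software, its background setting and the array's chip position are not given in the sources used here. Of 22523 probes, 13793 carried 1 gene symbol, none carried several and 8730 carried none in the annotation used. The symbols came from the platform annotation, and 13752 of them were matched through their Entrez identifier to the RefSeq gene table. No coordinates were used, because no genome build was tied to the probes.

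The array of female control replicate 2 held no usable signal. Its highest intensity was 83.2 and 1115 probes (5%) passed the detection threshold, and the deposited log2 table held no numbers for it. The design fixed before the data were examined named all 47 arrays. This array was left out after its values were seen, so the fit of 46 arrays reported here was a later choice, and the fit of all 47 that the design named is given beside it as an alternative, over the same probes. Over the 46 fitted arrays, 5921 to 8770 probes were detected (median 7310.5), and the 95th percentile of the raw intensity ran from 205 to 914. The number of arrays limits the precision of every comparison. No pair of arrays held identical values, and the highest correlation between any pair was 0.9896.

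Intensities were background corrected by the normexp model of limma with negative controls inferred from the detection p-values and an offset of 16, quantile normalized over the 46 arrays and put on the log2 scale. A probe was tested when its detection p was below 0.05 on at least 7 arrays, which left 9416 probes, 6786 of them with a symbol, for 6673 symbols. For the 106 symbols with more than 1 tested probe, the values are of the probe with the highest mean. A group-means model of the 6 groups was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 40 residual degrees of freedom. It gave 13 contrasts, each with two-sided p-values adjusted by the method of Benjamini and Hochberg over the 9416 probes and called at 0.05. Exposed means the average of the minimal and extreme response groups. Errors of log2 differences are standard errors (SE) from the model, and adjusted p-values of single genes are from limma throughout. The offset draws differences of dim probes toward 0. Where a probe was detected on no array of a group, the ratio is given as a lower bound against the lowest detected signal of each array.

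For each comparison the named genes were chosen by a rule fixed before the data were examined. They were the 12 probes with the largest rise and the 12 with the largest fall among the called probes with 1 symbol, 2 to 4 members of each gene list with the smallest p, and the glucocorticoid genes Fkbp5, Tsc22d3 and Sgk1. Where fewer than 5 probes passed, the 5 with the smallest p were added as values that did not pass. The glucocorticoid receptor gene Nr3c1 did not pass the detection filter. From the genes the rule gave, a smaller number is printed here.

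Before the data were examined, 27 gene lists were written from textbook knowledge, and 26 had at least 3 tested members. They covered glucocorticoid-induced genes, the glucocorticoid receptor with its chaperones and cofactors, heat shock proteins, immediate early genes, inflammation and NF-kB genes, interferon-stimulated genes, MHC class II genes, cell cycle genes, ribosomal protein genes, oxidative phosphorylation genes, proteasome genes, circadian clock genes, heme synthesis genes, unfolded protein response genes, adrenergic and cAMP signalling genes, oxidative stress defence genes, apoptosis regulators and globins. They also covered markers of neutrophils, monocytes, T cells, B cells, NK and cytotoxic cells, platelets, erythroid cells, and eosinophils, basophils and mast cells. The list of Y-linked genes and Xist had 0 probes, so the sex given in the labels was not checked against expression. A list's score on an array was the mean of its members' log2 values, each centred on its mean over all arrays. The difference of scores between groups was tested by a two-sided exact permutation test within a sex, and by 100000 resamples for comparisons that joined both sexes, with 1e-05 as the smallest p they can give. List p-values were adjusted over the 26 lists of each comparison. The camera test of limma, which compares a list with the other genes, was run with a preset correlation between genes of 0.01 and with an estimated correlation. The count of members called over all probes is given with the count adjusted over the list alone.

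On simulated data for the 9416 probes, in which 67 were changed by 0.5 on the log2 scale, 67 by 1 and 66 by 2, the fit of female extreme against minimal response recovered 44.8% of the probes changed by 0.5 and 100% of those changed by 1. That of male extreme against minimal response recovered 46.3% and 95.5%. In simulated list scores for female extreme against minimal response, 78 of 100 lists shifted by 2 SD were called, as were 4 of 420 unshifted ones.

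The alternatives fixed beforehand were no background correction, an offset of 50, normalization of each sex by itself, scaling to the 75th percentile in place of quantiles, the authors' deposited log2 values, a detection p below 0.01, probes detected on all fitted arrays, no filter, a fit of each sex by itself, a variance moderation with trend and robust options, array weights, the replicate number as a block, cell marker scores as covariates, and each array left out in turn. For lists they were z scores, both camera tests, the authors' values and residuals after cell marker scores. The fit of all 47 arrays was the design fixed beforehand. Chosen after seeing the data were the fit of 46 arrays, the fits without 4 female control arrays or without male extreme response replicate 6, and array brightness as a covariate. The 4 female control arrays (replicates 1, 3, 4 and 5) were picked because their expression stood apart, so a fit without them is not an independent test. List and array computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.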

Results

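Whole-blood gene expression was profiled in male and female rats after exposure to the scent of a predator, a model of traumatic stress. The questions stated for the series were how exposure itself, and how individual differences in behaviour after exposure, related to gene expression in blood. Exposed rats of each sex were classed by the submitters as showing a minimal or an extreme behavioural response, and unexposed rats served as controls. After 1 array without signal was left out, a choice made once its values had been seen, 6 female control rats and 8 rats in each of the other 5 groups were compared. Detection reached 5921 to 8770 of 22523 probes per array, and 9416 probes were tested. The median over arrays of the 95th percentile of raw intensity was 329 in female controls, 590 and 439 in females of minimal and extreme response, and 450, 344 and 545 in the male control, minimal and extreme response groups.

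**Figure D1:**
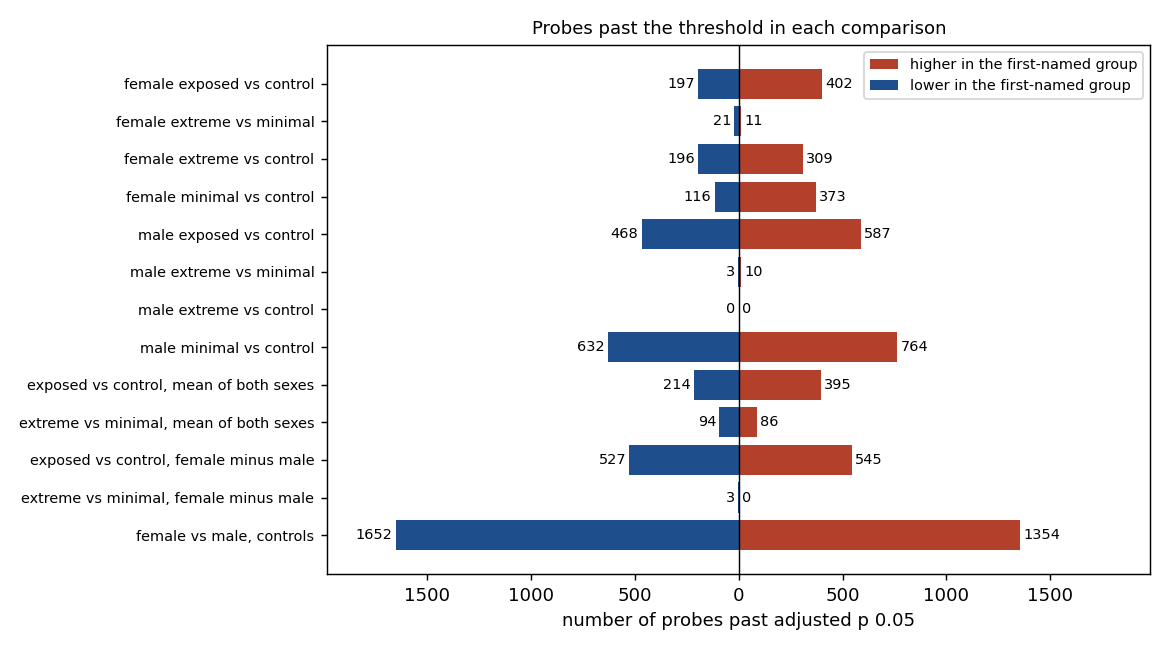
Number of probes past an adjusted p of 0.05 (x axis, out of 9416 tested) in each of the 13 comparisons (y axis), with bars to the right for probes higher and to the left for probes lower in the first-named group. The female against male control comparison had 1354 higher and 1652 lower probes, and the male extreme against control comparison had 0.

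The first comparison asked how exposure related to blood expression in females. Platelet genes were higher and immediate early genes lower in exposed than in control females. Slc6a4, the serotonin transporter that loads platelets with serotonin, was 5.04-fold higher (log2 difference 2.33 ± 0.34 SE, n = 16 exposed and 6 control rats, adjusted p = 4.51e-06), and lay above the control mean in 16 of 16 exposed rats. Alox12, the platelet 12-lipoxygenase, rose by 2.17 ± 0.31, and the von Willebrand factor gene Vwf by 1.95 ± 0.30. Fos, an early-response transcription factor gene, changed by −2.59 ± 0.39 (adjusted p = 8.03e-06) and Egr1, another, by −2.32 ± 0.36. The chemokine gene Ccl3 was lower (adjusted p = 1.36e-07), with no size given because it was detected on 5 of 6 control but 1 of 16 exposed arrays. The interleukin gene Il1b changed by −1.41 ± 0.25 (adjusted p = 0.000103, lower in 15 of 16).

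Of 9 platelet markers, 8 rose and 1 did not pass, and 8 rose when adjusted over the list alone. Examples were Gp5 (1.88 ± 0.27), a subunit of the platelet receptor for von Willebrand factor, and the platelet chemokine gene Ppbp (1.86 ± 0.32). The platelet score was 1.49 higher (exact permutation test, adjusted p = 0.0129). Of 12 immediate early genes, 7 fell and 5 did not pass, with 8 lower when adjusted over the list alone, and Junb changed by −2.14 ± 0.25. The score difference was −0.93 (exact permutation test, adjusted p = 0.00314). Of 13 inflammation and NF-kB genes, 3 fell, 1 rose and 9 did not pass, with the same counts adjusted over the list alone. The risen member was Sod2, the mitochondrial superoxide dismutase (1.37 ± 0.35, adjusted p = 0.00772), whose call was lost without female control replicate 3 or 4. That list's score difference was −0.26 (exact permutation test, adjusted p = 0.0129, and adjusted p = 0.275 with an estimated correlation). The 16 glucocorticoid-induced genes had a score difference of −0.25 that did not pass (adjusted p = 0.0579). Fkbp5, a glucocorticoid-induced cochaperone of the glucocorticoid receptor, differed by 0.36 ± 0.15 (adjusted p = 0.17). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, differed by −0.09 ± 0.14 (adjusted p = 0.781) and Sgk1, a kinase gene induced by corticosteroids, by −0.32 ± 0.15 (adjusted p = 0.237), so neither passed. The skeletal muscle genes Acta1 and Ckm were also higher in exposed females, Acta1 by 2.97 ± 0.68 (adjusted p = 0.00256) and Ckm at least 4.84-fold (adjusted p = 0.00349, detected on 0 of 6 control arrays).

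In limma, 599 probes passed, 402 higher and 197 lower, and scaling to the 75th percentile gave 514 higher and 48 lower. The platelet and immediate early gene differences rested on 4 of the 6 female control arrays. The rise of Ckm did not, since it was detected on 0 of the 6. Replicates 1, 3, 4 and 5 had immediate early gene scores of 0.91 to 1.29 and platelet scores of −2.44 to −1.06, against −0.05 and 0.01, and 0.48 and 0.22, in replicates 6 and 7. Without those 4 arrays 1 probe passed, and Slc6a4 differed by 0.33 ± 0.35, Fos by 0.06 ± 0.36 and Junb by −0.42 ± 0.22. By exact permutation 0 lists then passed, with adjusted p = 0.765 for immediate early genes and 0.965 for platelet markers. That test had few splits with replicates 6 and 7 as the only controls, and a list could hardly pass after adjustment. The 0 lists therefore cannot show that the list differences vanished. With cell marker scores as covariates 0 probes passed, and Junb differed by −0.73 ± 0.28 (adjusted p = 0.711).

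**Figure D2:**
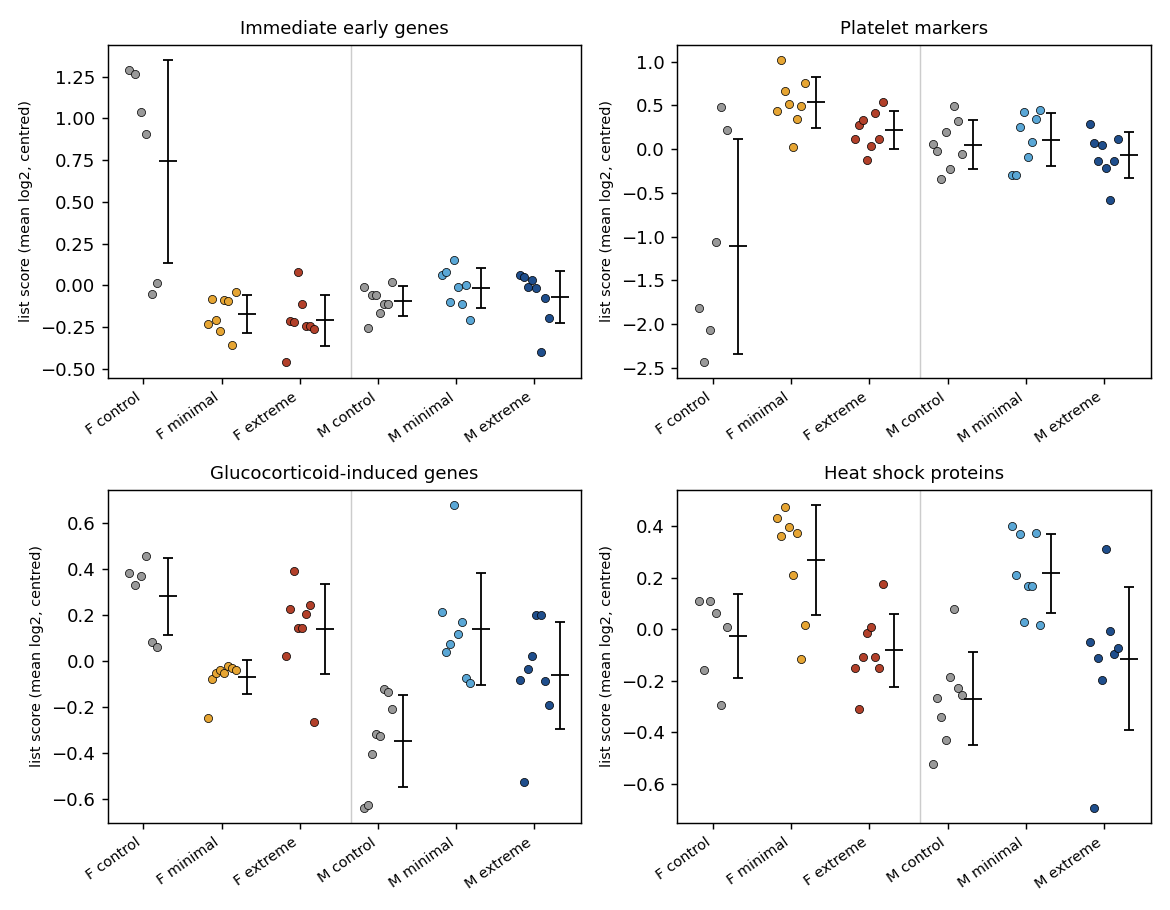
Score of each array (y axis, mean of the members' centred log2 values) for 4 gene lists in the 6 groups (x axis), with 1 point per rat and the group mean ± SD beside the points. In the panels of immediate early genes and platelet markers, 4 of the 6 female controls lie apart from the rats of other groups, with platelet scores of −2.44 to −1.06.

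Each female response group was then set against the same controls. In females of extreme response, Slc6a4 (2.22 ± 0.38) and Gp5 (1.89 ± 0.30) were higher than in controls, and G0s2, a lipolysis inhibitor gene, was lower (−2.32 ± 0.26, adjusted p = 1.53e-07). Fkbp5 rose by 0.68 ± 0.17 (adjusted p = 0.00978, higher in 7 of 8). Ccl3 was detected on none of the extreme response arrays and was at least 2.19-fold lower. Of 9 platelet markers, 8 rose, 1 did not pass and 8 rose when adjusted over the list alone, but the score difference of 1.33 did not pass (exact permutation test, adjusted p = 0.0779, and adjusted p = 0.0404 with an estimated correlation). Of 12 immediate early genes, 7 fell, 5 did not pass and 8 were lower when adjusted over the list alone, among them Fos (−2.50 ± 0.44) and Junb (−2.28 ± 0.28), with a score difference of −0.95 (exact permutation test, adjusted p = 0.0173). Of 13 inflammation and NF-kB genes, 2 fell, Il1b (−2.01 ± 0.28) and Ccl3, 11 did not pass, and 2 were lower when adjusted over the list alone. That score differed by −0.31 (exact permutation test, adjusted p = 0.00866, and adjusted p = 0.368 with an estimated correlation). Of 9 MHC class II genes, which present antigen to helper T cells, 2 fell and 7 did not pass, with 6 lower when adjusted over the list alone. RT1-DMa changed by −0.69 ± 0.19, a call lost without female control replicate 7, and RT1-DMb by −0.53 ± 0.16, a call lost in 8 of 14 omissions of 1 array. The MHC class II score differed by −0.47 (exact permutation test, adjusted p = 0.0404, and adjusted p = 0.379 with an estimated correlation). By array it ran from −1.08 to −0.52 at extreme response and from −0.64 to −0.05 in control replicates 1, 3, 4 and 5. It was 0.12 and 0.18 in control replicates 6 and 7, so this difference did not rest on the former 4 arrays. On residuals after cell marker scores neither the inflammation score (adjusted p = 0.0629) nor the MHC class II score (0.0524) passed, and with the authors' deposited values the MHC class II score did not (0.0693).

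In females of minimal response, Alox12 (2.52 ± 0.35), Ppbp (2.27 ± 0.36) and Gp9 (2.04 ± 0.35), another subunit of the von Willebrand factor receptor, were higher than in controls. The monocyte receptor gene Cd14 was lower (−1.23 ± 0.24, adjusted p = 0.000277). Of 9 platelet markers, 8 rose, 1 did not pass and 8 rose when adjusted over the list alone, with a score difference of 1.65 (exact permutation test, adjusted p = 0.0289). Of 12 immediate early genes, 5 fell, 7 did not pass and 7 were lower when adjusted over the list alone, among them Fos (−2.69 ± 0.44) and Junb (−2.01 ± 0.28), with a score difference of −0.91 (exact permutation test, adjusted p = 0.00866), and adjusted p = 0.121 on residuals after cell marker scores. Of 16 glucocorticoid-induced genes, 1 rose, 1 fell and 14 did not pass, with 1 higher and 6 lower when adjusted over the list alone. Dusp1, a phosphatase gene that dampens MAP kinase signalling, changed by −1.71 ± 0.31, while Nfkbia (−0.76 ± 0.25, adjusted p = 0.0614) and Fkbp5 (0.03 ± 0.17, adjusted p = 0.956) did not pass. That score differed by −0.35 (exact permutation test, adjusted p = 0.00866, and adjusted p = 0.342 with an estimated correlation), and its direction turned to 0.02 when arrays were scaled to the 75th percentile.

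By limma, 505 probes passed for extreme response (309 higher, 196 lower) and 489 for minimal response (373 higher, 116 lower), against the same 6 controls. Without the 4 female control arrays described above, 7 and 0 probes passed and 0 lists passed in either, Fos for extreme response differed by 0.15, Slc6a4 by 0.22 ± 0.37, G0s2 by −1.24 ± 0.31 (adjusted p = 0.158), RT1-DMa by −1.12 ± 0.27 (adjusted p = 0.136) and Fkbp5 by 0.64 ± 0.26 (adjusted p = 0.467). For minimal response Egr1 then differed by 0.10, Alox12 by 0.56 ± 0.25 and Cd14 by −0.90 ± 0.34 (adjusted p = 0.936). With replicates 6 and 7 as the only controls, the exact permutation test had few splits, and a list could hardly pass after adjustment. The 0 lists therefore cannot show that the list differences vanished. With cell marker scores as covariates 6 and 0 passed, array weights gave 312 for extreme response, and scaling to the 75th percentile gave 247 (224 higher, 23 lower) and 692 (600 higher, 92 lower).

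The question of individual differences among exposed females was addressed by extreme against minimal response. In the sample titles the rat numbers of the female groups did not overlap, with controls lowest and extreme response highest. Those of the male response classes did overlap. What the numbers stand for is not given. In females, neither class nor exposure can be told apart from an order of animals or handling that followed them. The controls do not enter its group means, but they share its normalization and its estimate of the spread. Klf9, a transcription factor gene induced by glucocorticoids, rose by 1.24 ± 0.20 (2.36-fold, n = 8 and 8, adjusted p = 0.00138), and Cd14, the monocyte receptor for bacterial lipopolysaccharide, by 1.11 ± 0.22 (adjusted p = 0.0112), each higher in 8 of 8. Btk, a kinase gene of B cells and myeloid cells, changed by −1.08 ± 0.21 (adjusted p = 0.00967) and Sirpa, a myeloid inhibitory receptor gene, by −0.74 ± 0.14 (adjusted p = 0.0112). The MHC class I gene RT1-CE16 rose by 1.54 ± 0.33 (adjusted p = 0.0218), but not without female minimal response replicate 8 or female extreme response replicate 4. Il1b changed by −1.21 ± 0.26 (adjusted p = 0.0218), but not without female minimal response replicate 6 or female extreme response replicate 2 or 4.

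Among 16 glucocorticoid-induced genes, 3 rose, 13 did not pass, and 5 were higher and 2 lower when adjusted over the list alone. The risen members were Klf9, Pik3ip1, an inhibitor of PI3 kinase (0.73 ± 0.18, adjusted p = 0.0474), and Fkbp5 (0.65 ± 0.16, adjusted p = 0.0495, higher in 7 of 8). The list's score difference of 0.21 did not pass (exact permutation test, adjusted p = 0.0737), and neither did Tsc22d3 (0.29 ± 0.15, adjusted p = 0.437) or Sgk1 (−0.34 ± 0.16, adjusted p = 0.361). Among 17 interferon-stimulated genes, 3 fell, 14 did not pass, and 6 were lower when adjusted over the list alone. They were the antiviral gene Mx2 (−1.47 ± 0.36), Stat2, which carries the interferon signal (−0.70 ± 0.16), and Gbp2 (−0.64 ± 0.15), while the score difference of −0.26 did not pass (adjusted p = 0.0808). Near the threshold, the calls of Fkbp5, Pik3ip1, Mx2, Stat2 and Gbp2 were lost in 13, 12, 15, 9 and 12 of 16 omissions of 1 array.

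The scores of 3 lists were lower at extreme response, each with adjusted p = 0.0283 by exact permutation and adjusted p = 0.162 with an estimated correlation, although 0 of their members passed in limma over all probes. MHC class II genes differed by −0.46, with 6 of 9 lower when adjusted over the list alone, such as Ciita, their master regulator (−0.81 ± 0.21, adjusted p = 0.0639), and RT1-Ba (−0.65 ± 0.19, adjusted p = 0.12). Heat shock proteins differed by −0.35, with 3 of 6 lower when adjusted over the list alone, such as the cochaperone gene Dnaja1 (−0.91 ± 0.23, adjusted p = 0.0574). Neutrophil markers differed by −0.31, with 2 of 13 lower when adjusted over the list alone, such as the NADPH oxidase subunit gene Ncf1 (−0.57 ± 0.15, adjusted p = 0.0755), while the chemokine receptor gene Cxcr2 differed by −0.70 ± 0.21 (adjusted p = 0.12). On residuals after cell marker scores, which include the neutrophil score, 0 lists passed, with −0.33 (adjusted p = 0.0604) for heat shock proteins and −0.19 (adjusted p = 0.14) for MHC class II genes, and with the authors' deposited values MHC class II genes did not pass (adjusted p = 0.0566).

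In limma, 32 probes passed (11 higher, 21 lower). The count was 18, 8, 49 and 13 without female minimal response replicates 5, 6, 7 and 8, and 18, 14, 7 and 69 without female extreme response replicates 1, 2, 4 and 8. It was 0 when arrays were scaled to the 75th percentile or all 47 were fitted, with 1156 probes at a raw p below 0.05 in the fit of 46, and 5 with cell marker scores as covariates or with each sex fitted by itself, 11 with no filter, 19 with array brightness, 53 with an offset of 50, 74 without the 4 female controls and 96 with array weights.

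**Figure D3:**
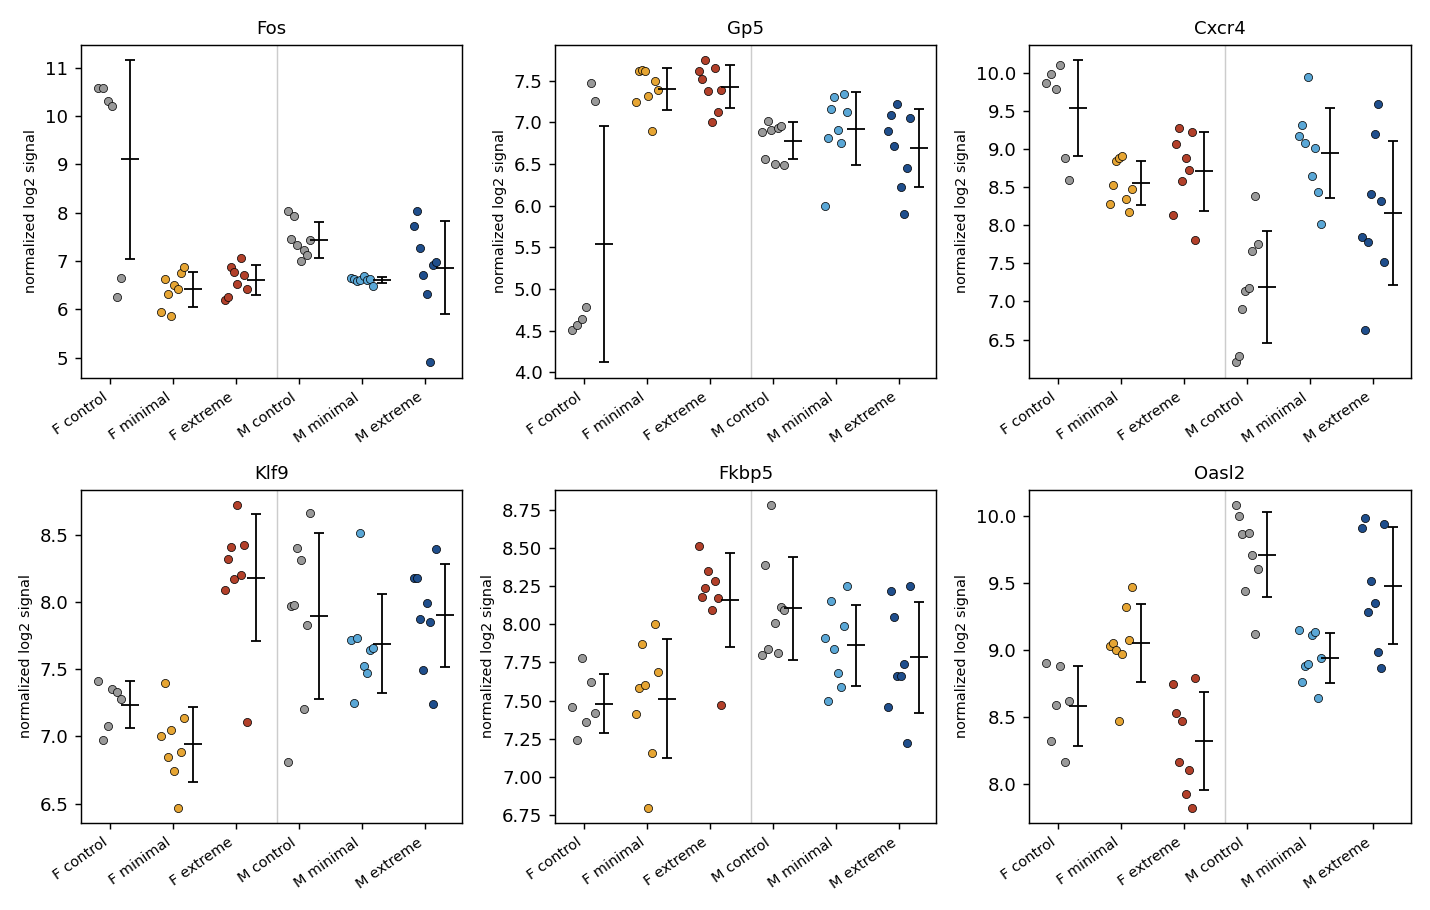
Normalized log2 signal (y axis) of 6 genes in the 6 groups (x axis), with 1 point per rat and the group mean ± SD beside the points. Klf9 was 1.24 and Fkbp5 0.65 higher in females of extreme than of minimal response, and Oasl2 differed between the sexes in that comparison by −1.27.

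In males, exposed rats were likewise set against controls. Rgs18, a regulator of G-protein signalling of platelets and their precursors, rose by 1.39 ± 0.29 (2.62-fold, n = 16 exposed and 8 control rats, adjusted p = 0.00188, higher in 14 of 16), and Cxcr4, a chemokine receptor that governs leukocyte homing, by 1.37 ± 0.27 (adjusted p = 0.00122, higher in 15 of 16). Rgs2, another regulator of G-protein signalling, rose by 1.21 ± 0.21 (adjusted p = 0.000588, higher in 16 of 16) and the chaperone-binding gene Cacybp by 1.28 ± 0.21 (adjusted p = 0.000227). Sod2 rose by 1.24 ± 0.31. Acaa2, an enzyme of mitochondrial fatty acid oxidation, and Adipor2, an adiponectin receptor gene, each changed by −0.86 ± 0.16 (adjusted p = 0.000686 and 0.00112).

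Of 16 glucocorticoid-induced genes, 7 rose and 9 did not pass, with the same counts adjusted over the list alone. They included Cxcr4, Dusp1 (1.18 ± 0.25), Nfkbia, the inhibitor of NF-kB (0.91 ± 0.20), the anti-inflammatory gene Anxa1 (0.66 ± 0.16) and Tsc22d3 (0.46 ± 0.13, adjusted p = 0.0163), the last not called without male control replicate 1. Fkbp5 (−0.28 ± 0.14, adjusted p = 0.192) and Sgk1 (0.20 ± 0.14, adjusted p = 0.377) did not pass. The glucocorticoid-induced gene score rose by 0.39 (exact permutation test, adjusted p = 0.00873, and adjusted p = 0.264 with an estimated correlation). Of 11 oxidative stress defence genes, 4 rose and 7 did not pass, with 5 higher when adjusted over the list alone. The list was led by the glutathione reductase gene Gsr (1.28 ± 0.20, adjusted p = 0.000126), and its score rose by 0.27 (exact permutation test, adjusted p = 0.0023, and adjusted p = 0.264 with an estimated correlation). Of 6 heat shock proteins, 4 rose, 2 did not pass and 4 were higher when adjusted over the list alone, such as Dnaja1 (0.77 ± 0.20) and the mitochondrial chaperonin gene Hspd1 (0.53 ± 0.15), but the score difference of 0.32 did not pass (adjusted p = 0.0645). Of 9 platelet markers in exposed males, 0 passed, and the score difference was −0.03 (exact permutation test, adjusted p = 0.807). Of 12 immediate early genes, Zfp36 and Klf4 rose and 10 did not pass, and the score difference of 0.05 did not pass (adjusted p = 0.498). The muscle genes Ckm (−1.86 ± 0.58, adjusted p = 0.0307), Tnnt3 (−1.30 ± 0.37, adjusted p = 0.0176) and Pygm (−0.94 ± 0.25, adjusted p = 0.0102) were lower in exposed males. The Ckm call was lost without male control replicate 1, 2, 4 or 7, and that of Tnnt3 without male control replicate 2. In limma 1055 probes passed (587 higher, 468 lower), against 167 (115 higher, 52 lower) with scaling to the 75th percentile and 119 with all 47 arrays.

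In males of minimal response against controls, Cxcr4 rose by 1.76 ± 0.31 (3.39-fold, adjusted p = 0.000182, n = 8 and 8), Rgs18 by 1.79 ± 0.33 and the phosphatase subunit gene Ppp1cc by 1.52 ± 0.19 (adjusted p = 2.24e-06), each higher in 8 of 8. Nrp1, a semaphorin coreceptor gene, changed by −1.21 ± 0.27 and Reep5, which shapes the endoplasmic reticulum, by −1.35 ± 0.26. Of 16 glucocorticoid-induced genes, 7 rose and 9 did not pass, also when adjusted over the list alone, among them Dusp1 (1.62 ± 0.29), Nfkbia (1.26 ± 0.23) and Tsc22d3 (0.67 ± 0.15). The glucocorticoid-induced gene score rose by 0.49 (exact permutation test, adjusted p = 0.00404, and adjusted p = 0.241 with an estimated correlation). Of 6 heat shock proteins, 4 rose and 2 did not pass, also when adjusted over the list alone, such as Dnaja1 (1.12 ± 0.23) and Hspd1 (0.84 ± 0.17). The heat shock score rose by 0.48 (exact permutation test, adjusted p = 0.00404, and adjusted p = 0.241 with an estimated correlation). Of 11 oxidative stress defence genes, 4 rose and 7 did not pass, also when adjusted over the list alone, such as Gsr (1.59 ± 0.23) and the heme oxygenase gene Hmox1 (0.71 ± 0.20). That score rose by 0.29 (exact permutation test, adjusted p = 0.00404, and adjusted p = 0.361 with an estimated correlation), although the list's median was −0.02.

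Of 23 proteasome genes, whose products degrade tagged proteins, 6 fell and 17 did not pass in the same comparison, with 10 lower when adjusted over the list alone. Psmb6 changed by −0.64 ± 0.11, Psmb7 by −0.63 ± 0.14 and Psmd1 by −0.52 ± 0.12, and the score by −0.20 (exact permutation test, adjusted p = 0.00505, and adjusted p = 0.241 with an estimated correlation). Of 13 unfolded protein response genes, 3 rose and 10 did not pass, with 4 higher when adjusted over the list alone, such as the endoplasmic reticulum chaperone gene Hspa5 (0.39 ± 0.098) and Herpud1 (0.53 ± 0.14). The unfolded protein response score rose by 0.16 (exact permutation test, adjusted p = 0.0331, and adjusted p = 0.384 with an estimated correlation). In limma 1396 probes passed (764 higher, 632 lower), against 544 (276 higher, 268 lower) with scaling to the 75th percentile and 317 with all 47 arrays.

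In males of extreme response against controls, 0 probes passed in limma, with 1437 at a raw p below 0.05 and a smallest adjusted p of 0.0621. The 5 genes with the smallest p were Lztr1 (−0.59 ± 0.12), Fut4, a fucosyltransferase gene of myeloid cells (0.68 ± 0.14), Dvl1, a transducer of Wnt signals (−0.77 ± 0.17), the phosphorylase kinase subunit gene Phkg2 (−0.62 ± 0.14) and Cacybp (1.04 ± 0.24), and none passed. No list passed either, the smallest adjusted p by exact permutation being 0.133 for oxidative stress defence genes (0.25). The count was 28, 47 and 3 without male control replicates 6, 7 and 8, and 105, 302 and 272 without male extreme response replicates 1, 2 and 8. It was 149 with array weights, 98 with cell marker scores, 23 over probes detected on all fitted arrays, 19 without the 4 female controls, 16 with array brightness and 1 with the replicate number as a block.

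Males of extreme and minimal response differed in 13 probes (10 higher, 3 lower). The proteasome subunit gene Psmb6 rose by 0.53 ± 0.11, Pih1d1, a cofactor in the assembly of protein complexes, by 0.75 ± 0.17, and the vesicle transport genes Trappc1 and Stx8 each by 0.51 ± 0.11. Saraf, a regulator of store-operated calcium entry, changed by −0.52 ± 0.12. Each had an adjusted p of 0.0445 in limma and went the same way in 8 of 8 rats. Fkbp5 (−0.08, adjusted p = 0.891), Tsc22d3 (−0.42 ± 0.15, adjusted p = 0.206) and Sgk1 (−0.29 ± 0.16, adjusted p = 0.46) did not pass, and no list passed, the smallest adjusted p by exact permutation being 0.112. None of the 5 called genes named here kept its call in every omission of 1 array. The count was 4, 0, 0, 22, 1, 0 and 26 without male minimal response replicates 1, 2, 4, 5, 6, 7 and 8, and 3, 0, 1, 24, 92, 23 and 0 without male extreme response replicates 1, 2, 3, 4, 5, 6 and 8. It was 0 with all 47 arrays, with 1187 probes at a raw p below 0.05 in the fit of 46, and 1 with trend and robust moderation, 2 with scaling to the 75th percentile or each sex fitted by itself, 7 with no filter, 26 without the 4 female controls, 33 with array brightness and 38 over probes detected on all fitted arrays.

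Averaged over both sexes, Rgs18 was higher in exposed rats by 1.36 ± 0.21 (2.57-fold, adjusted p = 4.8e-05, higher in 29 of 32). The thrombin receptor gene F2rl2 was higher by 1.32 ± 0.21 and Ppbp by 1.24 ± 0.21. Fos changed by −1.65 ± 0.26 (lower in 30 of 32), and S100a6, a calcium-binding protein gene, by −0.85 ± 0.12 (adjusted p = 1.1e-05, lower in 31 of 32). Of 9 platelet markers, 7 rose, 2 did not pass and 8 rose when adjusted over the list alone, with Gp5 at 0.95 ± 0.18. The platelet score rose by 0.73 (permutation test, adjusted p = 0.0186, and adjusted p = 0.136 with an estimated correlation). Of 12 immediate early genes, 4 fell and 8 did not pass, also when adjusted over the list alone, with Ier2 at −0.77 ± 0.14. The immediate early gene score changed by −0.44 (permutation test, adjusted p = 0.0186, and adjusted p = 0.0545 with an estimated correlation). By sex, the platelet score difference was 1.49 in females and −0.03 in males, and that of immediate early genes −0.93 and 0.05, and neither passed in males. Of 6 heat shock proteins, 1 rose (Hspd1, 0.35 ± 0.11, adjusted p = 0.0424, a call lost in 22 of 46 omissions), 5 did not pass and 3 rose when adjusted over the list alone. The heat shock score rose by 0.22 (permutation test, adjusted p = 0.0493, and adjusted p = 0.381 with an estimated correlation). Of 11 adrenergic and cAMP signalling genes, 1 rose (Prkar1a, a regulatory subunit of protein kinase A, 0.44 ± 0.09) and 10 did not pass, also when adjusted over the list alone. The adrenergic score rose by 0.07 (permutation test, adjusted p = 0.0478, and adjusted p = 0.695 with an estimated correlation). On residuals after cell marker scores the immediate early (adjusted p = 0.108) and adrenergic (0.31) scores did not pass, scores in SD units lost the adrenergic (0.102) and heat shock (0.0767) calls, and the authors' deposited values lost the heat shock call (0.061).

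The other 22 lists did not pass in that comparison. Score differences were 0.10 for oxidative stress defence genes (adjusted p = 0.172), 0.07 for glucocorticoid-induced genes and −0.04 for inflammation and NF-kB genes (0.609 each). They were −0.23 for MHC class II genes and −0.08 for ribosomal protein genes (adjusted p = 0.172 each), −0.07 for proteasome genes (0.172), 0.07 for unfolded protein response genes (0.226), −0.04 for oxidative phosphorylation genes (0.276) and −0.11 for interferon-stimulated genes (0.392). They were −0.06 for the glucocorticoid receptor with its chaperones (0.431), −0.10 for heme synthesis genes (0.6), −0.09 for erythroid markers (0.605), −0.07 for B cell markers (0.6), 0.06 for monocyte markers, 0.05 for NK and cytotoxic cell markers, −0.03 for globins and 0.03 for cell cycle genes (0.609 each). They were −0.03 for circadian clock genes (0.676), −0.02 for T cell markers (0.907), 0.01 for neutrophil markers (0.944), −0.01 for eosinophil, basophil and mast cell markers (0.985) and 0 for apoptosis regulators (0.995). In limma 609 probes passed (395 higher, 214 lower). The count was 2 without the 4 female controls and 5 with cell marker scores as covariates, and 0 lists passed without those controls, while S100a6 then differed by −0.86 ± 0.15 (adjusted p = 0.012). Rgs18 then differed by 0.82 ± 0.25 (adjusted p = 0.134), F2rl2 by 0.63 ± 0.24, Ppbp by 0.37 ± 0.22, Gp5 by 0.04 ± 0.14, Prkar1a by 0.15 ± 0.098, Fos by −0.33 ± 0.21 and Ier2 by −0.49 ± 0.18. All 47 arrays gave 402, and scaling to the 75th percentile 475 (420 higher, 55 lower).

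Extreme against minimal response was also averaged over both sexes, with 16 rats on each side. Klf9 rose by 0.72 ± 0.14 (adjusted p = 0.00968, higher in 14 of 16), Gpr4, a proton-sensing receptor gene, by 0.99 ± 0.20 (higher in 16 of 16), and Car1, the carbonic anhydrase of red cells, by 0.89 ± 0.19 (higher in 16 of 16). By sex, Klf9 passed in females only. In males 0 of the 16 glucocorticoid-induced genes rose past the threshold, and 5 were lower when adjusted over the list alone. F2rl2 changed by −1.09 ± 0.23, the actin-severing gene Gsn by −0.83 ± 0.19 and Btk by −0.72 ± 0.15. Of 6 heat shock proteins, 2 fell, 4 did not pass and 4 were lower when adjusted over the list alone. They were Dnaja1 (−0.80 ± 0.16, lower in 15 of 16) and Dnajb1 (−0.43 ± 0.12, adjusted p = 0.039, a call lost in 16 of 32 omissions). The heat shock score changed by −0.34 (permutation test, adjusted p = 0.00052, and adjusted p = 0.0499 with an estimated correlation). Of 39 oxidative phosphorylation genes, 2 rose and 37 did not pass, also when adjusted over the list alone. They were the cytochrome oxidase subunit genes Cox5b (0.25 ± 0.069) and Cox4i1 (0.26 ± 0.071), called with an adjusted p of 0.042 and 0.0432 and lost in 18 and 20 of 32 omissions. The oxidative phosphorylation score rose by 0.08 (permutation test, adjusted p = 0.00533, and adjusted p = 0.0499 with an estimated correlation).

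Of 13 unfolded protein response genes, 1 rose, 2 fell and 10 did not pass over both sexes, with 1 higher and 5 lower when adjusted over the list alone. Asns, the asparagine synthetase gene, rose by 0.86 ± 0.19, while Ddit3, a transcription factor gene of that response, changed by −0.52 ± 0.11 and the disulfide isomerase gene Pdia6 by −0.52 ± 0.11. The unfolded protein response score changed by −0.15 (permutation test, adjusted p = 0.00953, and adjusted p = 0.073 with an estimated correlation). Of 23 proteasome genes, 1 rose (Psmb6, 0.37 ± 0.079) and 22 did not pass, with 5 higher when adjusted over the list alone. The proteasome score rose by 0.11 (permutation test, adjusted p = 0.0175, and adjusted p = 0.0562 with an estimated correlation). Of 16 cell cycle genes, 0 passed in limma and 1 was higher when adjusted over the list alone. The cell cycle score rose by 0.12 (permutation test, adjusted p = 0.0314, and adjusted p = 0.202 with an estimated correlation), a call lost on residuals after cell marker scores (0.057) and with scores in SD units (0.0773). In limma 180 probes passed (86 higher, 94 lower). The count was 3 with scaling to the 75th percentile, 2 with all 47 arrays, 27 with cell marker scores, 52 with no filter and 291 without the 4 female controls. It was 106 and 97 without female minimal response replicates 2 and 6, 78, 109 and 80 without female extreme response replicates 1, 2 and 4, 117, 117 and 102 without male minimal response replicates 1, 4 and 7, and 56 and 118 without male extreme response replicates 2 and 8.

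The sexes were compared directly for the exposure difference, as females minus males. The control arrays used here are also those of the baseline comparison of control females and males below, so the 2 comparisons are not independent. Dusp1 differed by −2.96 ± 0.38 (adjusted p = 1.87e-06), Zfp36, which destabilises inflammatory messenger RNAs, by −2.42 ± 0.34, Cxcr4 by −2.28 ± 0.40 and Il1b by −2.01 ± 0.34. Mean log2 Dusp1 was 10.92 in female and 8.19 in male controls. It was 9.21 and 9.06 in females of minimal and extreme response, and 9.81 and 8.92 in such males. For Zfp36 the means were 8.86 and 6.45 in controls, 7.7 and 7.35 in these females and 7.71 and 7.37 in these males. Both genes thus differed more between the control groups than between the exposed groups. Vwf differed by 2.41 ± 0.40 and Gp5 by 1.85 ± 0.36. The muscle gene Ckm also differed (adjusted p = 0.000576), with no size given because it was detected on 0 of 6 female control arrays. The platelet score differed by 1.52 (7 of 9 members higher, 0 lower, and 8 higher when adjusted over the list alone, adjusted p = 0.00515, and adjusted p = 0.171 with an estimated correlation). Immediate early genes differed by −0.99, with Junb at −2.26 ± 0.34 (0 of 12 higher, 6 lower, and 7 lower when adjusted over the list alone). That list had an adjusted p of 0.00026, from the smallest p the resamples can give, and adjusted p = 0.0366 with an estimated correlation. Glucocorticoid-induced genes differed by −0.63 (adjusted p = 0.00052, and adjusted p = 0.18 with an estimated correlation), with 6 of 16 lower, such as Nfkbia (−1.64 ± 0.29), and Fkbp5 higher (0.63 ± 0.20, adjusted p = 0.0348), with 8 lower and 1 higher when adjusted over the list alone. The Fkbp5 call was lost without female control replicate 1, 3 or 5 or male control replicate 2 or 4. Inflammation and NF-kB genes differed by −0.43 (2 of 13 lower, 3 when adjusted over the list alone, adjusted p = 0.00104, and adjusted p = 0.18 with an estimated correlation), and oxidative stress defence genes by −0.35 (2 of 11 lower, 5 when adjusted over the list alone, adjusted p = 0.00136, and adjusted p = 0.18 with an estimated correlation), with Cat, the catalase gene, at −1.26 ± 0.30. List p-values here are from permutation tests. In limma 1072 probes differed (545 higher, 527 lower), against 543 with all 47 arrays, 499 (446 higher, 53 lower) with scaling to the 75th percentile, 1 with cell marker scores, and 0 without the 4 female controls. Without those controls Vwf differed by 0.62 ± 0.32, Gp5 by 0.02 ± 0.29, Dusp1 by −1.41 ± 0.38, Zfp36 by −0.93 ± 0.33, Cxcr4 by −1.48 ± 0.52, Junb by −0.53 ± 0.25 and Il1b by −0.75 ± 0.37. Nfkbia, at −1.19 ± 0.40, Cat, at −0.92 ± 0.40, and Fkbp5, at 0.59 ± 0.28, moved by less than 1.5 times, and none of these genes passed (adjusted p = 0.224 or more). Ckm did not pass either (adjusted p = 0.224 in limma). Its estimate, which includes undetected arrays, hardly moved, at 4.62 ± 1.2 against 4.63 in the main fit. The inflammation list (adjusted p = 0.029) and the oxidative stress list (0.0164) then passed by permutation, and immediate early genes (0.104), glucocorticoid-induced genes (0.104) and platelet markers (0.974) did not.

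For extreme against minimal response, the difference itself differed between females and males in 3 probes, each more negative in females. They were the interferon-induced genes Oasl (−1.32 ± 0.26, adjusted p = 0.0329) and Oasl2 (−1.27 ± 0.23, adjusted p = 0.0105) and the uridine phosphorylase gene Upp1 (−1.07 ± 0.22, adjusted p = 0.0329). No list passed, the smallest adjusted p by permutation being 0.0884 for glucocorticoid-induced genes (0.41). Oasl2 kept its call in all 32 omissions of 1 array, and Oasl and Upp1 lost theirs in 16 and 17. The count was 1 without any of female minimal response replicates 6, 7 and 8, female extreme response replicates 3, 4, 5 and 6, male minimal response replicates 2, 3, 6, 7 and 8, or male extreme response replicates 1, 2 and 8. It was 8 without female extreme response replicate 8 or male extreme response replicate 6, and 5 without male extreme response replicate 7. It was 0 with all 47 arrays, scaling to the 75th percentile or cell marker scores, 1 with no filter, 6 over probes detected on all fitted arrays or with the replicate number as a block, and 12 with array weights. Across the 9416 probes, which are not independent replicates, the exposure differences of the sexes correlated at r = −0.11 (37 of 100 regroupings were as large in size, range −0.30 to 0.27), and the differences of extreme against minimal response at r = 0.26 (4 of 100, range −0.30 to 0.32). The latter was 0.11 with scaling to the 75th percentile.

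Control females and males, 6 and 8 rats, were compared as a baseline. The design named array batch as a possible confounder of this comparison. No batch is given, so sex cannot be told apart from a batch that differed between the sexes. Dusp1 was 6.61-fold higher in females (2.73 ± 0.31, adjusted p = 4.16e-08), Zfp36 was higher by 2.41 ± 0.29 and Cxcr4 by 2.35 ± 0.33. Ckm was at least 7.78-fold lower in females (adjusted p = 0.000286). Of 14 erythroid markers, 8 were higher, 0 lower and 6 did not pass, such as the anion exchanger gene Slc4a1 (1.64 ± 0.28) and the membrane protein gene Epb42 (1.13 ± 0.19). Of 9 MHC class II genes, 7 were lower and 2 did not pass, such as Cd74, the invariant chain (−1.09 ± 0.19), and RT1-Ba (−1.19 ± 0.21), and of 9 platelet markers 8 were lower and 1 did not pass, such as Gp1bb (−1.84 ± 0.30). Immediate early genes (7 of 12 higher, 1 lower), glucocorticoid-induced genes (9 of 16 higher, 3 lower), inflammation and NF-kB genes (3 of 13 higher, 2 lower) and oxidative stress defence genes (5 of 11 higher, 1 lower, with Cat at 1.83 ± 0.25) also differed by exact permutation, but no list of this comparison passed with an estimated correlation (adjusted p = 0.378 or more).

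Score differences in the controls were 0.74 for erythroid markers, −0.80 for MHC class II genes, −1.16 for platelet markers, 0.84 for immediate early genes, 0.63 for glucocorticoid-induced genes, 0.24 for inflammation genes and 0.33 for oxidative stress defence genes. They were −0.42 for B cell markers, with Cd79b, a chain of the B cell receptor, at −1.43 ± 0.37 and the other 8 not passing. They were 0.29 for cell cycle genes (4 of 16 higher, 2 lower, with Cdc20 at 1.23 ± 0.24) and 0.27 for circadian clock genes (1 of 5 higher). They were −0.15 for proteasome genes (3 of 23 higher, 8 lower, with Psmd1 at −0.95 ± 0.13) and −0.20 for the glucocorticoid receptor with its chaperones (2 of 9 lower). These 12 lists passed by exact permutation, with adjusted p from 0.00289 to 0.0447, and none with an estimated correlation. On residuals after cell marker scores the calls of MHC class II genes (0.301), cell cycle genes (0.375), the glucocorticoid receptor with its chaperones (0.0902) and oxidative stress defence genes (0.0743) were lost. Scores in SD units lost those of platelet markers (0.0548), cell cycle genes (0.0733), inflammation genes (0.132) and oxidative stress defence genes (0.0511). When adjusted over the list alone, the counts were unchanged except for inflammation genes, with 4 higher and 3 lower. In limma 3006 probes passed (1354 higher, 1652 lower). The count was 1990 over probes detected on all fitted arrays, 532 with cell marker scores and 201 without the 4 female controls. Without those controls 0 lists passed and the platelet score difference turned to 0.30. The exact permutation test then had few splits, and a list could hardly pass after adjustment. The 0 lists therefore cannot show that the list differences vanished. Without the 4 female controls Dusp1 differed by 1.17 ± 0.35 (adjusted p = 0.0606), Zfp36 by 0.92 ± 0.30, Cxcr4 by 1.56 ± 0.48 and Gp1bb by −0.20 ± 0.22. Cat (1.49 ± 0.37, adjusted p = 0.0222) and Psmd1 (−0.63 ± 0.17, adjusted p = 0.0393) passed. Scaling to the 75th percentile gave 568 higher and 1735 lower.

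**Figure D4:**
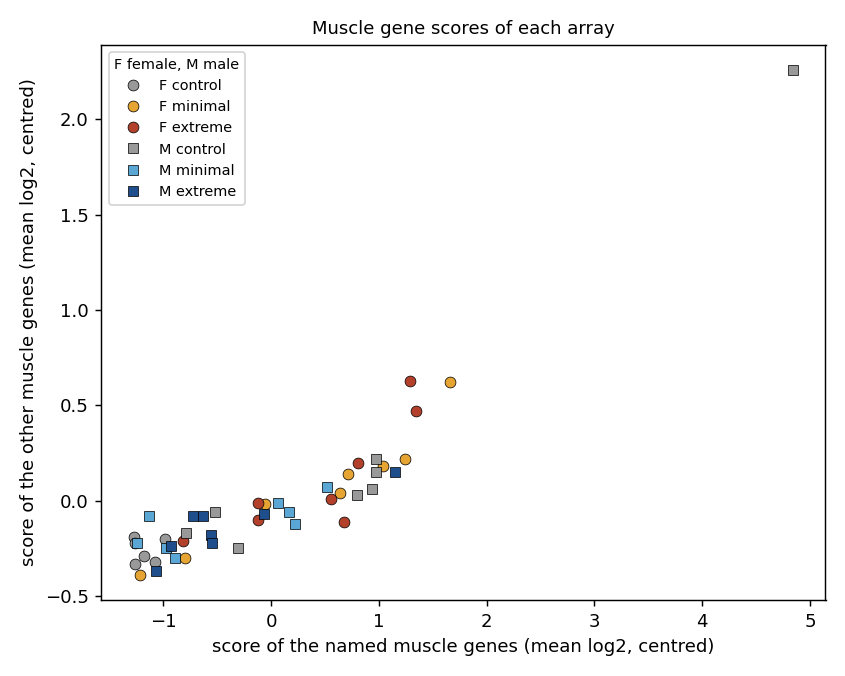
Score of 7 skeletal muscle genes named in the comparisons (x axis, mean centred log2) against the score of 17 other muscle genes (y axis, same unit), with 1 point per array, coloured by group, circles for females and squares for males. Male control replicate 2 lies farthest out, at 4.84 and 2.26.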

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

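The tests of explanations in this part, and the counts of other splits, were written down after the results they bear on had been seen, while the comparisons between the sexes were fixed beforehand.

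The exposure difference was compared between females and males. Its control arrays are also those of the baseline comparison of control females and males, so the 2 comparisons are not independent. In the fit of 46 arrays 1072 probes passed the test of the difference itself, and by permutation so did 5 lists: glucocorticoid-induced genes (−0.63), immediate early genes (−0.99), inflammation and NF-kB genes (−0.43), oxidative stress defence genes (−0.35) and platelet markers (1.52). With an estimated correlation only immediate early genes passed (adjusted p = 0.0366, against 0.171 for platelet markers and 0.18 for the other three lists). Without the 4 female control arrays set apart in the report, 0 probes and 2 lists passed (inflammation, adjusted p = 0.029, and oxidative stress, 0.0164), and with cell marker scores as covariates 1 probe passed. For extreme against minimal response, 3 probes differed between the sexes (Oasl, Oasl2 and Upp1).

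Single arrays lay far from the other arrays of their group in 15 of 180 combinations of group and measure, and chance gives about 1 in 20, or 9. Male extreme response replicate 6 accounted for 4, with 27.9% of probes detected (others 32.1 to 35.2), a ribosomal protein gene score of −0.57 (others −0.05 to 0.11), a heme synthesis score of −1.67 (others −0.16 to 0.13) and an MHC class II score of −0.43 (others 0.16 to 0.65). Male control replicate 2 had a score of 4.84 for the named muscle genes (others −0.79 to 0.97) and of 2.26 for other muscle genes (others −0.25 to 0.22). Male extreme response replicate 1 had a named muscle gene score of 1.15 (others −1.07 to −0.07). Male minimal response replicate 4 had a glucocorticoid-induced gene score of 0.68 (others −0.10 to 0.21), and female minimal response replicate 1 one of −0.25 (others −0.08 to −0.02). The circadian clock score was −0.27 in female minimal response replicate 5 (others −0.02 to 0.11) and 0.16 in male control replicate 3 (others −0.22 to −0.05). Female minimal response replicate 7 had an apoptosis regulator score of −0.23 (others 0 to 0.13), and female minimal response replicate 4 an interferon score of −0.31 (others 0.02 to 0.19). Female extreme response replicate 3 had a heme synthesis score of −0.08 (others 0.24 to 0.43), and female extreme response replicate 4 a monocyte score of 0.93 (others −0.29 to 0.11).

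The first pattern weighed is the contrast of exposed with control females, high in immediate early and low in platelet transcripts in 4 of 6 controls. Array brightness as the whole cause was argued against by the 516 probes called with brightness in the fit, against 599 without it. Fewer platelets in the control blood, as the whole cause of the immediate early gene difference, were neither shown nor excluded. The platelet gene Gp5 read 4.51 to 4.78 in the 4 controls, near the level of undetected probes, and 7.47 and 7.26 in replicates 6 and 7. A linear removal of marker scores may therefore take out too little. The immediate early gene score difference was −0.93 (exact permutation test, adjusted p = 0.00314) before removal of cell marker scores and −0.31 (adjusted p = 0.0265) after. It still passed, but the call was then lost for minimal response against control (−0.27, adjusted p = 0.121) and for exposure over both sexes (−0.13, 0.108). Removal of those scores in the fit of single genes ended the 599 calls, with Slc6a4 going from 2.33 ± 0.34 to 0.53 ± 0.27, Junb from −2.14 ± 0.25 to −0.73 ± 0.28 (adjusted p = 0.711), Fos from −2.59 ± 0.39 to −0.71 ± 0.49 (adjusted p = 0.9) and the median SE from 0.145 to 0.213, so both a smaller difference and a larger error ended them. Exposure as the whole cause was argued against by the split among controls, none of them exposed. Platelet scores were −2.44 to −1.06 in those 4 controls, but 0.48 and 0.22 in control replicates 6 and 7. Group means were 0.53 and 0.21 in females of minimal and extreme response and 0.05 in male controls. Immediate early gene scores were 0.91 to 1.29 in the 4, and −0.05 and 0.01 in replicates 6 and 7. A partial share of exposure was not excluded. A different way of drawing or holding the control blood stays open as untested, because the labels give no collection batch.

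The second pattern is that males of minimal response differed from controls in 1396 probes and those of extreme response in 0. Brightness, a single array and cell composition were each argued against as the whole cause of that gap, because the extreme response count was 16 with brightness in the fit, 302 without male extreme response replicate 2 and 98 with cell marker scores. The direct comparison of the 2 response groups gave 13 probes, so few probes were shown to differ between these groups themselves. The model used a shared spread per probe, with a median SE of 0.152 for each response group against control. That SE was the same for both classes by construction, so it cannot show whether they varied alike. A difference in the size of the response between behavioural classes is what the direct comparison above tested. Its count of 13 ran from 0 to 92 when 1 array was left out, so smaller differences were neither shown nor excluded.

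The third pattern is the muscle genes in blood. The score of 17 muscle genes outside the 7 named ones followed the named score over the 46 arrays (Pearson r = 0.91, Spearman rho = 0.90, permutation p = 1e-05 each, the smallest the resamples can give, and r = 0.87 without the 2 farthest arrays). This is consistent with muscle tissue carried into some blood samples, a hypothesis whose gene list was written after the named genes were seen. For a rise with exposure in both sexes, neither muscle score in males went its way, since the 17 other muscle genes differed by 0.34 (exact permutation p = 0.0116) in exposed females and by −0.41 (p = 0.0128) in exposed males, with 15 of 17 lower. It was not excluded, because without male control replicate 2 the male difference was −0.13 (exact permutation p = 0.0732), and the named genes, at −0.71 (p = 0.0413) without that array, had been chosen for their differences.

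Other splits of the same arrays into groups of the same sizes were fitted, 100 for each comparison with the real one included. Only the real split reached the real count in 10 comparisons. The smallest share that 100 splits can give is 1 of 100. Chance was thus made less likely as the source of these counts and not ruled out, least where another split came close. The real count and the highest other were 599 and 59 for exposed females, 32 and 7 for female extreme against minimal response, 505 and 356 for female extreme response against control, 489 and 473 for female minimal response against control, and 1396 and 22 for male minimal response against control. Over both sexes they were 609 and 2 for exposure and 180 and 48 for extreme against minimal response, between the sexes 1072 and 57 for exposure and 3 and 1 for extreme against minimal response, and 3006 and 1954 for control females against males. For exposed males 2 of 100 splits were as large (1055, highest other 1416), and for male extreme against minimal response 3 of 100 (13, highest other 24). These shares lie under 0.05, but other splits called more probes than the real ones, so chance was made less likely there and not ruled out. For male extreme response against control all 100 splits had as many as the 0 observed, the highest with 45, so chance was not excluded.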

How the results depend on the processing

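The reported fit of 46 arrays, the fits without the 4 female control arrays or male extreme response replicate 6, and array brightness as a covariate were chosen after seeing the data. The design fixed before named all 47 arrays, and the other alternatives were fixed before too. Quantile-normalized signals without background correction equalled the authors' deposited values, so where both were run they were counted once. Of 202 values of probe counts under alternatives, 143 stayed within 1.5 times the reported count and 59 moved, of 32 values of correlations between the sexes 30 stayed, and of 91 counts of called lists 58 stayed. Of 307 values of called lists, 204 kept direction and side of the threshold, 101 lost the threshold and 2 reversed. Of 2422 values of the genes printed in the text, 2045 kept both, 331 lost the threshold, 38 gained it and 8 reversed. Over all genes the naming rule gave, with up to 1551 values under an alternative, 31 reversed without the 4 female control arrays, 27 with cell marker scores, 13 with all 47 arrays, 2 with scaling to the 75th percentile and 0 under each other alternative. Where fewer arrays or probes entered a fit, or a covariate took up variation, the construction changed the test. For the other changes the cause was not tested. The chip of each array was not given, so the planned fit with the chip as a block was not run. Signal over background limited the analysis to 9416 of 22523 probes.

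With all 47 arrays, as the design named, probe counts were 0 for female extreme against minimal response, 119 for exposed males, 0 for male extreme against minimal response, 317 for male minimal response against control, 402 for exposure and 2 for extreme against minimal response over both sexes, and 543 and 0 for the differences between the sexes in these comparisons. RT1-DMb turned to 0.18 for female extreme response against control. The added array held no signal. Scaling to the 75th percentile gave 0 for female extreme against minimal response, 247 for female extreme response against control, 167 for exposed males, 2 for male extreme against minimal response, 544 for male minimal response against control, 3 for extreme against minimal response over both sexes, and 499 and 0 for the differences between the sexes. The correlation between the sexes for extreme against minimal response was 0.11. No scaling moved the median of all probes by more than 0.08 in size.

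Without the 4 female control arrays, counts were 1 for exposed females, 74 for female extreme against minimal response, 7 and 0 for female extreme and minimal response against control, 26 for male extreme against minimal response, 19 for male extreme response against control, 2 for exposure and 291 for extreme against minimal response over both sexes, 0 for the difference between the sexes in exposure and 201 for control females against males. The correlation between the sexes for exposure was 0.03. Lists called were 0 for exposed females, 0 for both female response groups against control, 0 for exposure over both sexes, 2 for the difference between the sexes and 0 for control females against males. Where the exact permutation test was used, few splits remained with replicates 6 and 7 as the only female controls. A list could then hardly pass after adjustment, so those counts of 0 do not show that the differences vanished. The platelet score difference was 0 for exposure over both sexes and 0.30 for control females against males. For exposed females Fos was 0.06, Egr1 0.24 and Sod2 −0.17, Fos was 0.15 for female extreme and Egr1 0.10 for female minimal response against control. Of the 599 probes called for exposed females, 81.3% kept their sign, at a median ratio of 0.33. Without male extreme response replicate 6, counts were 23 for male extreme against minimal response and 8 for its difference between the sexes, and lists called were 8 for extreme against minimal response over both sexes and 2 for the difference between the sexes.

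Cell marker scores as covariates gave 0 for exposed females, 5 for female extreme against minimal response, 6 and 0 for female extreme and minimal response against control, 98 for male extreme response against control, 5 for exposure and 27 for extreme against minimal response over both sexes, 1 and 0 for the differences between the sexes, and 532 for control females against males. Sod2 for exposed females turned to −0.39 and Gp9 for female minimal response against control to −0.07. Gp9 is a member of the platelet list, whose score was a covariate, so its shrinkage was built in. The neutrophil, T cell, B cell, platelet and erythroid lists, whose scores were removed, were not tested on residuals. Lists called on residuals after these scores were 0 for female extreme against minimal response, 1 each for female extreme and minimal response against control, 4 for exposed males, 1 for male extreme response against control, 1 for exposure over both sexes, 1 for the difference between the sexes in extreme against minimal response and 7 for control females against males.

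Array brightness gave 19 for female and 33 for male extreme against minimal response, and 16 for male extreme response against control. Array weights gave 96 for female extreme against minimal response, 312 for female and 149 for male extreme response against control, and 12 for the difference between the sexes in extreme against minimal response. Over probes detected on all 46 arrays the counts were 38 for male extreme against minimal response, 23 for male extreme response against control, 6 for the difference between the sexes in extreme against minimal response and 1990 for control females against males. With no filter they were 11 for female and 7 for male extreme against minimal response, 52 over both sexes and 1 for the difference between the sexes. A fit of each sex by itself gave 5 for female and 2 for male extreme against minimal response, an offset of 50 gave 53 for the female one, and trend and robust moderation gave 1 for the male one.

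The replicate number within each sex as a block was not run for control females against males. In the other 12 comparisons it gave 1 for male extreme response against control and 6 for the difference between the sexes in extreme against minimal response, and moved none of the remaining 10 counts by over 1.5 times. Arrays with the same number did not deviate together, with a mean correlation of −0.04 in females and 0.02 in males and 1 of 20 and 6 of 24 pairs over 0.1, and 1 of 22 and 4 of 24 arrays correlated best with their own number, so the numbers were not taken to pair the samples.

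For lists, the camera test with a preset correlation called 11 for female extreme against minimal response, 1 for exposed males, 4 for male extreme against minimal response, 1 for male extreme and 3 for male minimal response against control, 5 for the difference between the sexes in extreme against minimal response and 5 for control females against males. With an estimated correlation it called 0 for female extreme against minimal response, 0 for exposed males, 0 for male minimal response against control, 0 for exposure and 2 for extreme against minimal response over both sexes, 1 for the difference between the sexes in exposure and 0 for control females against males. The authors' deposited values gave 6 lists for exposed males. Scores in SD units gave 6 for female extreme against minimal response and 2 for exposure over both sexes.

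With each array left out in turn, counts ran from 7 to 69 for female and from 0 to 92 for male extreme against minimal response, from 0 to 302 for male extreme response against control, from 56 to 268 for extreme against minimal response over both sexes and from 1 to 8 for its difference between the sexes. The other 8 counts stayed within 1.5 times, with ranges of 409 to 803 for exposed females, 344 to 694 and 352 to 671 for female extreme and minimal response against control, 793 to 1373 for exposed males, 1089 to 1553 for male minimal response against control, 475 to 770 for exposure over both sexes, 740 to 1290 for its difference between the sexes and 2446 to 3097 for control females against males.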

Other observations

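Genes called in both sexes were counted for exposure, after the results were seen and without a test. Higher in exposed rats of both sexes were 31 probes, where independent lists of 402 and 587 would share 25.1, and among them were Rgs18, the thrombin receptor gene F2rl2 and Sod2. Lower in both were 4, where 9.79 would be shared, namely S100a6, the calcium-binding protein gene, Commd4, Kxd1 and Rab43. Another 43 probes were called in opposite directions, where independent lists would give 32.3. For minimal response against control, 59 probes were higher in both sexes (30.3 for independent lists), 6 were lower in both (7.79) and 22 were opposite (34.4 for independent lists). The sexes share no arrays, so these overlaps carry no shared controls. They do share the normalization and the estimate of spread per probe, which the numbers for independent lists do not allow for.

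Of the 7 muscle genes named, which had been named for such differences, 7 were higher in exposed than in control females, 2 of them past the threshold, and 7 were lower in exposed than in control males, 5 past it. Of 17 other muscle genes, 15 were higher in exposed females and 15 lower in exposed males, with 1 past the threshold in each sex. The named score exceeded every female control array in 15 of 16 exposed females, and the other muscle score did so in 13 of 16. Taken as deviations from the group means, the 2 scores still correlated (r = 0.90, permutation p = 1e-05, and r = 0.83 without the 2 farthest arrays).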
